A study of Mus musculus with 35 samples.

How the data were processed

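RNA was sequenced in bulk from punches of the medial prefrontal cortex (mPFC), a cortical area that takes part in social behaviour, of wild-type (WT) mice and mice deficient in Shank3 (KO), per the labels. The labels divide 35 libraries into 8 groups, each a genotype and a treatment: water as control, antibiotics (abx), acetate, or antibiotics with acetate (abx_and_acetate). They also give each library a sex (15 females, 20 males) and an RNA integrity number (RIN) between 8.8 and 9.3. Per the labels' protocols, RNA was extracted with spin columns, made into strand-marking libraries and read as paired ends. Each library has its own label, but the labels do not say that each came from a separate animal, so p-values measure the spread between these samples. Replicates are numbered in the order of the sample records, a number that only names a library and pairs none. A library is called by its group and number, as in WT_abx 4.

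The deposited matrix holds log2 CPM, read counts scaled to library size, for 14870 named genes in 35 columns, each matched to a sample by its title; no row lacks a name and 0 columns were left unused. The authors' values have the form that voom gives, log2 of the reads plus 0.5 over an effective library size: 100% of the values came out as whole reads within a tolerance of 0.01, which also gave each library's depth. The recovered depth was 12.8 to 28.0 M (mega) reads over these genes, with a median of 21.8 M. The submitters' processing notes name limma, with no version. The aligner, the counting tool, whether counting used strand, the genome build and the filter on low genes are not given in the sources used here. Some 12 rows repeat another row's values (23 rows in such sets), and 23 names had been turned into dates before deposit; these rows stayed in the tests under the deposited names. Of the deposited symbols, 14427 (97.0%) matched the GENCODE vM21 annotation of GRCm38, which was used here for positions only. A log2 value near the floor rests on few reads: 0.5 read stands at -4.67 in the shallowest library and -5.83 in the deepest, and 851 genes had a mean below 0.

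Each gene was tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with no added pseudocount and no further filter. All 35 libraries entered 1 fit with 8 group means and sex as an additive term, and the moderated test used a prior variance that follows the mean. The sex term took the labelled sex, also for the libraries whose Y-linked genes went against it. No fit took sex from expression. The 16 comparisons were KO against WT in each treatment and over treatments, each treatment against control and abx_and_acetate against abx within each genotype, and 3 genotype-by-treatment interactions. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. A log2 fold is given with its standard error (SE) from that fit, and a group mean with its standard deviation (SD). Shank3 was also tested with an exact 2-sided permutation test in each treatment. Correlations of genotype effects between treatments run across genes, which are not independent replicates, and were set against 100 draws in which genotypes were reassigned within each treatment.

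Gene lists were fixed from the labels before the data were examined, and 45 of them had enough measured members to test. The test was camera in limma with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The same test with a correlation estimated from the data, and fry, which asks whether a list's genes move on balance in 1 direction without setting them against other genes, stand beside it. Fry's mixed test asks whether they change in either direction. Members were also counted with p-values adjusted over the list alone. A list score is a library's mean deviation, over the members, from each member's mean across libraries. Of 213 list results past the preset threshold among 720, those described in the text were chosen after their values were seen.

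The rule for named genes was fixed at the same time. It takes the genes past the threshold, or, where more than 24 pass, the 12 higher and 12 lower with the largest log2 fold among those with a mean of at least 0, of which the text prints a part. Where few pass, it adds the genes with the smallest unadjusted p in each direction, and in each list described the 3 members with the smallest p; these are given as values. Shank1, Shank2 and Shank3 are named throughout. Acr in the acetate comparison, C730034F03Rik and the Y-linked genes were singled out after their values were seen.

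The statistics were tested on simulated data with 100 genes changed at each of 2 sizes. In a simulated comparison of KO with WT in control, 62% of genes changed by 0.5 on the log2 scale and 89% of those changed by 1 were called, with 13 unchanged genes called. The shares were 49% and 85% in abx_and_acetate against abx in KO (8 unchanged called), 65% and 91% in acetate against control in KO (4 unchanged called), and 63% and 80% in abx_and_acetate against control in WT (9 unchanged called). Genes were drawn independently of each other, and many were changed at once, which makes the adjusted threshold easier to pass. The shares may therefore be too high for the real comparisons, where most had few calls. Other settings tried were no sex term, RIN or the range of the number in the sample title added, libraries centred on their median, genes with a mean below 0 left out, a pseudocount of 1 on the linear scale, 1 prior variance for all genes, sample quality weights, voom weights on the recovered reads, the groups compared fitted alone, and each library left out in turn. Fits without the 3 WT libraries of intermediate Shank3, without the 4 libraries whose Y-linked genes go against their sex label, and without both sets were added after seeing the data. No library was left out of the results given unless said.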

Results

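The series asked how acetate, a short-chain fatty acid made by gut bacteria, and depletion of those bacteria with antibiotics change transcription in the mPFC of mice with and without Shank3. Bulk RNA-seq of 35 mPFC libraries gave log2 CPM values for 14870 genes. The groups were WT_control (n = 6), KO_control (n = 4), WT_abx (n = 4), KO_abx (n = 3), WT_acetate (n = 5), KO_acetate (n = 5), WT_abx_and_acetate (n = 4) and KO_abx_and_acetate (n = 4). Depth ran from 12.8 M reads in WT_abx_and_acetate 4, the shallowest library, to 28.0 M in WT_control 3; the mean per group lay between 20.1 and 23.8 M. The first 4 principal components held 12%, 9.18%, 8.08% and 7.89% of the variance. On component 1, KO_control 1 (-44.6) and the library labelled WT_abx 4 (-38.9) lay farthest out, and on component 2 KO_acetate 1 (60.2).

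Shank3 encodes a scaffold protein of the postsynaptic density and lies on chromosome 15 from 89499623 to 89560261 (GRCm38, plus strand). It was lower in every KO library, at 4.07 to 5.11 log2 CPM in 16 libraries, than in every library labelled WT, where it ran from 7.48 to 8.85. The log2 fold was -3.92 ± 0.17 (SE) in control, with 4.65 ± 0.33 in KO (SD, n = 4) and 8.57 ± 0.20 in WT (SD, n = 6), which is 15.1-fold lower. It was -3.48 ± 0.20 under antibiotics, -3.94 ± 0.16 under acetate and -4.02 ± 0.19 under antibiotics with acetate. Exact permutation tests gave p = 0.00476 in control, p = 0.00794 under acetate and p = 0.0286 under each of the other treatments, each the smallest p that the group sizes allow. Which exons the mutation removes is not given in the sources used here, and the values cover the whole gene. Its relatives Shank1 and Shank2 passed the threshold in none of the 16 limma comparisons; their log2 folds ran from -0.38 to 0.14 and from -0.38 to 0.21, and the smallest adjusted p was 0.255 for each.

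Acr, which encodes the sperm protease acrosin, is the gene downstream of Shank3 on the same strand (chromosome 15, 89568326 to 89574585). It was at 5.04 to 5.78 log2 CPM in the KO libraries and at -0.46 to 0.83 in 16 WT libraries. In 3 libraries both genes lay between these levels: the library labelled WT_abx 4 (Shank3 7.48, Acr 4.56), the library labelled WT_acetate 2 (7.80, 4.46) and the library labelled WT_acetate 5 (8.08, 3.62), against 8.22 to 8.85 for Shank3 in the other 16. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y went against the sex label in 4 libraries. The libraries labelled WT_acetate 2 and WT_acetate 4 are male by label and had means of -1.55% and -1.01% of the male level; the library labelled WT_abx 3 is female by label and had 98.5%. The library labelled WT_acetate 5, female by label, had 29.9%. All stayed in their labelled groups and under their labelled sex in the tests.

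**Figure D1:**
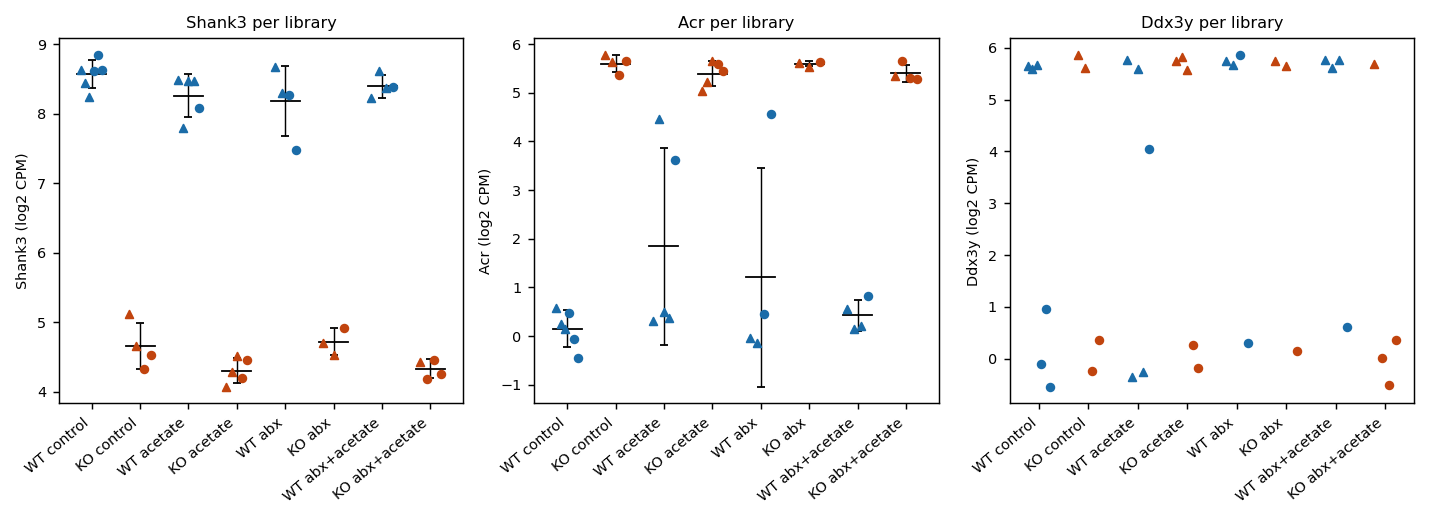
Shank3, Acr and Ddx3y in log2 CPM (vertical axes) in each library, by group (horizontal axes); blue is WT, orange KO, circles are libraries labelled female, triangles male, and the black line and bars are the group mean ± SD, drawn for Shank3 and Acr only. Acr lies at 5.04 to 5.78 in KO and below 0.83 in WT, apart from 3 libraries labelled WT at 3.62, 4.46 and 4.56.

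Without treatment, KO mPFC differed from WT in 3 genes by limma: Shank3, Acr and Fgl1. Acr was higher by 5.45 ± 0.65 (43.7-fold, adjusted p = 1.52e-05), at 5.60 ± 0.17 in KO (SD, n = 4) and 0.15 ± 0.38 in WT (SD, n = 6). Fgl1, which encodes a secreted fibrinogen-like protein and lies on chromosome 8 (41191434 to 41215156), was higher by 2.08 ± 0.37 (adjusted p = 0.0178), with all 4 KO libraries (1.34 to 2.22) above all 6 WT libraries (-0.91 to 0.55). Immediate early genes, which neurons transcribe within minutes of activity, had a negative log2 fold in KO for 27 of 29 members, with a median of -0.97 (adjusted p = 8.91e-32 with the preset correlation and adjusted p = 0.0557 with an estimated correlation). The list scores were -0.869 and -0.735 in the KO_control males against 0.122 to 0.333 in the WT_control males, and 0.0118 and 0.327 in the KO_control females against 0.824 to 1.02 in the WT_control females. The transcription factor Junb was at -1.36 ± 0.30, the transcription factor Egr2 at -2.47 ± 0.59 and the kinase Sik1 at -1.15 ± 0.28.

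For the immediate early list fry gave an adjusted p = 0.0891 and its mixed test an adjusted p = 0.00591. Over the list alone, 20 members passed as lower and 1 as higher, and 0 passed over all genes; 14 passed as lower without KO_control 1 or KO_control 2. Fitted on the control libraries alone, limma called 23 genes, 3 higher and 20 lower, with Junb (adjusted p = 0.0035), Egr2 (adjusted p = 0.00402) and Sik1 (adjusted p = 0.0035) among them. At an unadjusted p under 0.05 the fit on all libraries held 595 genes, where chance alone gives 744. Fgl1 lost its call without WT_control 1 (adjusted p = 0.0673), WT_control 4 (0.081), WT_control 5 (0.0831), KO_control 1 (0.274), KO_control 2 (0.0795) or KO_control 4 (0.0782).

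Glucocorticoid-responsive genes had 17 positive log2 folds among 22 in untreated KO mPFC. The lipase inhibitor Angptl4 was at 1.38 ± 0.33 and the glucocorticoid receptor co-chaperone Fkbp5 at 1.03 ± 0.28, while the clock gene Per1 was at -0.66 ± 0.18. The list passed with the preset correlation (adjusted p = 0.000185) and not with an estimated correlation (adjusted p = 0.979). With p adjusted over the list alone, 6 members passed as higher and 2 as lower, and none over all genes. KO_control 1 had a list score of 1.32 against -0.13 to 0.28 in the other KO_control libraries. Without it the list turned direction (adjusted p = 0.82) and the counts over the list alone were 0 higher and 1 lower; without WT_control 3 they were 3 and 1.

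Under antibiotics, Acr again stood higher in KO than in WT, by 4.48 ± 0.77 (adjusted p = 0.0165), beside lower Shank3; these were the 2 genes past the threshold, against 562 at an unadjusted p under 0.05. The WT mean for Acr includes the library labelled WT_abx 4 at 4.56, the other 3 lying at -0.14 to 0.45; the Acr log2 fold, KO vs WT in abx, was 5.50 without that library (adjusted p = 8.64e-06, 3 genes). Fgl1 was at 1.89 ± 0.44 and the cilium-associated gene Armc2 at 0.64 ± 0.15, neither past the threshold; Fgl1 passed without the library labelled WT_abx 4 (adjusted p = 0.0274). Ribosomal protein genes had 75 of 77 log2 folds below 0 (median -0.19), such as Rpl28 at -0.24 ± 0.07 and Rpl31 at -0.34 ± 0.11. Nuclear genes of oxidative phosphorylation had 82 of 84 below 0 (median -0.16), such as the complex I subunit Ndufa6 at -0.28 ± 0.09 and the complex IV subunit Cox4i1 at -0.25 ± 0.08. All 6 blood markers were below 0 too (median -0.85), such as the haem synthesis gene Alas2 at -1.15 ± 0.42 and the globin gene Hba-a2 at -0.96 ± 0.40. Also below 0 were 21 of 22 endothelial (median -0.20), all 15 pericyte (-0.15), 17 of 20 astrocyte (-0.15) and 22 of 24 oligodendrocyte markers (-0.37) and all 13 mitochondrially encoded genes (-0.16); 17 lists passed with the preset correlation and 0 with an estimated correlation. Cholesterol synthesis genes had 22 of 24 below 0 (median -0.11), with the isomerase Idi1 at -0.45 ± 0.13, although the reductase Dhcr7 was at 0.18 ± 0.08.

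These 3 lists passed with the preset correlation (adjusted p = 3.98e-41, adjusted p = 9.07e-30 and adjusted p = 0.000287). With an estimated correlation they gave adjusted p = 0.371, adjusted p = 0.371 and adjusted p = 0.543. The blood list had an adjusted p = 2.19e-05 with the preset correlation and adjusted p = 0.413 with an estimated correlation, with 0 members past over the list alone and 1 without KO_abx 1. The library labelled WT_abx 4 had the highest ribosomal score of its group (0.213) and stood apart in the scores of meningeal (2.2) and choroid plexus markers (2.3). Adjusted over the list alone, 0 ribosomal, 0 oxidative phosphorylation and 1 lower cholesterol gene passed in limma; over all genes none did, with or without voom weights. The ribosomal count was 65 lower without the library labelled WT_abx 3, 39 without KO_abx 2 and 1 without KO_abx 3, and the oxidative phosphorylation count 5 without the library labelled WT_abx 3. The cholesterol count was 0 without WT_abx 1, WT_abx 2, KO_abx 1 or KO_abx 3. Acr lost its call without WT_abx 1 (adjusted p = 0.184), WT_abx 2 (0.128), the library labelled WT_abx 3 (0.148), KO_abx 1 (0.21), KO_abx 2 (0.189) or KO_abx 3 (0.0726). The count was then 1, except without KO_abx 3, where Gm2260 joined Shank3. Each of these fits kept the library labelled WT_abx 4, with Acr at 4.56.

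Under acetate, Shank3 was the 1 gene past the threshold between KO and WT, and 888 genes had an unadjusted p under 0.05. Acr was at 3.43 ± 0.64 (adjusted p = 0.0604), with the libraries labelled WT_acetate 2 and WT_acetate 5 in the WT group; it passed without the former (adjusted p = 0.000513, 2 genes) or the latter (adjusted p = 0.0279, 2 genes). All 24 oligodendrocyte and myelin markers were positive (median 0.75), such as the myelin regulator Myrf at 0.76 ± 0.32 and Opalin at 0.81 ± 0.35. All 19 markers of striatal medium spiny neurons were positive (median 0.60), with the dopamine receptors Drd1 at 1.07 ± 0.38 and Drd2 at 1.42 ± 0.58. Postsynaptic scaffold genes had 29 of 32 below 0 (median -0.12), among them Begain at -0.30 ± 0.09 and Shank2 at -0.35 ± 0.12 besides Shank3.

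The 3 lists passed with the preset correlation (adjusted p = 2.43e-14, adjusted p = 3.15e-09 and adjusted p = 2.39e-10), and each had an adjusted p = 0.481 with an estimated correlation. Over the list alone, limma called 0 oligodendrocyte, 0 striatal and 2 lower scaffold genes, Shank3 among them, and over all genes Shank3. The scaffold list holds Shank3 itself, the gene deficient in KO, so part of its result was fixed in advance. It was not tested without Shank3. KO_acetate 1 had list scores of 2.56 for striatal and 1.78 for oligodendrocyte markers, and a scaffold score of -0.432 against -0.208 to -0.0243 in the other KO_acetate libraries; without it the striatal list had an adjusted p = 0.438. The oligodendrocyte count was 19 without WT_acetate 3, 22 without KO_acetate 3 and 23 without KO_acetate 5, and the striatal count 1 without the library labelled WT_acetate 5 and 4 without KO_acetate 3. The scaffold count was 6 without KO_acetate 3, 5 without KO_acetate 5, and 1 without WT_acetate 3, the libraries labelled WT_acetate 4 or WT_acetate 5, KO_acetate 1, KO_acetate 2 or KO_acetate 4.

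Under antibiotics with acetate, 23 of 24 cholesterol synthesis genes had a positive log2 fold in KO relative to WT, with a median of 0.20. The final reductase Dhcr7 was at 0.37 ± 0.08, the farnesyl diphosphate synthase Fdps at 0.36 ± 0.09 and the mevalonate kinase Mvk at 0.33 ± 0.09. Acr was higher by 4.68 ± 0.73 (adjusted p = 0.00339), at 5.40 ± 0.17 in KO and 0.43 ± 0.32 in WT (SD, n = 4 each), and with Shank3 made up the 2 genes past the threshold, against 550 at an unadjusted p under 0.05. All 23 microglia markers were positive (median 0.16), such as the complement gene C1qb at 0.40 ± 0.13.

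The cholesterol list passed with the preset correlation (adjusted p = 3.16e-18), with an estimated correlation (adjusted p = 0.0215) and with fry (adjusted p = 0.02). With p adjusted over the list alone, 8 members passed, all higher, and none over all genes; without KO_abx_and_acetate 2 there were 5. Sex is unbalanced here: KO_abx_and_acetate has 3 females (list scores 0.136 to 0.221) and 1 male (0.00539), and WT_abx_and_acetate 1 female (-0.126) and 3 males (-0.0805 to 0.0313). The microglia list passed with the preset correlation (adjusted p = 1.19e-06) and not with an estimated correlation (adjusted p = 0.914), no member passed over the list alone, and 2 did without WT_abx_and_acetate 2. Without WT_abx_and_acetate 4, the shallowest library, its adjusted p = 0.141. Acr lost its call without KO_abx_and_acetate 1 (adjusted p = 0.0543), which left 1 gene. Its values did not overlap, at 5.28 to 5.65 in KO and 0.14 to 0.83 in WT. Its SE comes from the fit on all 35 libraries. That fit includes the libraries labelled WT_abx 4 (Acr 4.56), WT_acetate 2 (4.46) and WT_acetate 5 (3.62).

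Averaged over treatments, KO differed from WT in the same 3 genes as in control by limma: Shank3 (-3.84 ± 0.09, adjusted p = 1.43e-24), Acr (4.51 ± 0.35, adjusted p = 5.55e-10) and Fgl1 (1.78 ± 0.20, adjusted p = 2.46e-06). C730034F03Rik, upstream of Shank3 on chromosome 15 (89429589 to 89430868), was at 0.84 ± 0.16 (adjusted p = 0.0536) and Jun, an immediate early gene, at 0.37 ± 0.08 (adjusted p = 0.111). Jun passed without WT_abx_and_acetate 3 (adjusted p = 0.0493) or WT_acetate 1 (adjusted p = 0.0304). The count was 780 at an unadjusted p under 0.05, and 5 genes passed without WT_abx_and_acetate 3. Genotype effects correlated weakly across genes between treatments, with r = 0.151 for control and antibiotics, 0.144 for control and acetate, -0.00613 for control and both, -0.0969 for antibiotics and acetate, 0.0125 for antibiotics and both, and 0.149 for acetate and both. In 100 reassignments of genotype, r was as large in 16, 3, 48, 70, 54 and 9. Without Shank3 and Acr, r was 0.109, 0.107, -0.0619, -0.133, -0.0281 and 0.118 in the same order, and as large in 22, 5, 79, 78, 73 and 10 reassignments. Without KO_abx 3 the correlation for antibiotics and acetate was -0.25, and it turned positive without the libraries whose Y-linked genes go against their sex label.

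In WT mice, antibiotics alone left no gene past the threshold in limma, with or without voom weights, while 1345 genes had an unadjusted p under 0.05. Heat shock and protein folding genes had 23 of 25 negative log2 folds, with a median of -0.22 (adjusted p = 0.51 with an estimated correlation). The inducible chaperone Hspa1b was at -0.79 ± 0.23, the unfolded protein response factor Xbp1 at -0.36 ± 0.11 and the secreted factor Manf at -0.43 ± 0.13. Ribosomal protein genes had 74 of 77 positive log2 folds (median 0.17), such as Rpl4 at 0.17 ± 0.05. The replication fork protein Tipin was at 0.56 ± 0.11 and the Argonaute gene Ago3 at -0.61 ± 0.12 (adjusted p = 0.156 for each).

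Both lists passed with the preset correlation (adjusted p = 2.96e-11 and adjusted p = 1.82e-28), and each had an adjusted p = 0.51 with an estimated correlation. Adjusted over the list alone, 12 heat shock genes passed as lower and 0 ribosomal genes passed. The heat shock count was 1 without the library labelled WT_abx 4, 7 without the library labelled WT_abx 3, 3 without WT_control 1, 6 without WT_control 4, 4 without WT_control 5 and 5 without WT_control 6; it was 0 without the 3 libraries of intermediate Shank3. The ribosomal count was 47 without WT_control 1 and 62 without the library labelled WT_abx 3, and 1 gene passed over all genes without WT_abx 1. In this comparison 13 lists passed with the preset correlation and 0 with an estimated correlation. Cell type markers were among the 13: upper layer (Pou3f2 -0.29 ± 0.16), deep layer (Ntsr1 0.60 ± 0.29), pericyte (Atp13a5 0.35 ± 0.14) and meningeal (Aldh1a2 0.75 ± 0.63). The library labelled WT_abx 4 stood apart here too in its meningeal and choroid plexus scores.

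In KO mice, antibiotics left 2 genes lower by limma, Gm2897 (-1.53 ± 0.27) and the pseudogene Gm2260 (-3.76 ± 0.68), each with an adjusted p = 0.0374. Both lie on chromosome 14, Gm2897 from 3049285 to 3076840 and Gm2260 from 26016431 to 26025837. Gm2897 was at -0.68 ± 0.21 in KO_abx (SD, n = 3) and 0.84 ± 0.39 in KO_control (SD, n = 4), and Gm2260 at -2.12 ± 2.38 and 1.75 ± 0.29. Both are low genes whose values rest on few reads. The protocadherin Pcdha5, at -0.56 ± 0.14, was not past the threshold. The count at an unadjusted p under 0.05 was 491, below the 744 that chance gives.

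Neither Gm gene passed with voom weights on the recovered reads (0 genes), with RIN added (0 genes) or with a pseudocount of 1 (0 genes). The count was 0 without KO_control 1, KO_control 2, KO_control 3, KO_abx 1 or KO_abx 2, and 1 without KO_control 4 or KO_abx 3. The interaction of genotype with antibiotics held 0 genes in limma, with or without voom weights, and 368 at an unadjusted p under 0.05; 1 gene passed without KO_control 4, WT_abx 2 or KO_abx 3.

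In WT mice under acetate alone, 28 of 29 immediate early genes had a negative log2 fold against control, with a median of -0.72 (adjusted p = 0.638 with an estimated correlation). The prostaglandin synthase Ptgs2 was at -1.06 ± 0.26 and the transcription factors Fosl2 and Fosb at -0.86 ± 0.23 and -1.08 ± 0.30. The 1 gene past the threshold was Exosc1, a subunit of the RNA exosome on chromosome 19 (41922292 to 41933423). It was higher by 0.41 ± 0.07 (adjusted p = 0.0482), at 3.54 ± 0.12 in WT_acetate (SD, n = 5) and 3.11 ± 0.07 in WT_control (SD, n = 6). That call was lost with voom weights, a pseudocount of 1, these groups alone, or without the 4 libraries against their sex label. The ubiquitin ligase Hectd2 was at -0.51 ± 0.09 (adjusted p = 0.0516) and passed without WT_control 1 (0.03), WT_control 3 (0.0334) or WT_acetate 3 (0.0304); Fosl2 passed without WT_acetate 3 (0.0409). At an unadjusted p under 0.05 there were 1399 genes.

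The immediate early list passed with the preset correlation (adjusted p = 9.41e-17) and not with an estimated correlation (adjusted p = 0.638). Over the list alone, 16 members passed, all lower, and none over all genes; there were 2 without the 4 libraries that go against their sex label. The list count was 1 without WT_acetate 1, 9 without the library labelled WT_acetate 4, 4 without the library labelled WT_acetate 5 or without WT_control 5, and 5 without WT_control 4 or WT_control 6. Over all genes, 0 passed without WT_control 2, WT_control 4, WT_control 5, WT_control 6, WT_acetate 1 or the libraries labelled WT_acetate 4 or WT_acetate 5, and 0 with voom weights; 6 passed without WT_control 1, 4 without WT_control 3, 2 without the library labelled WT_acetate 2 and 3 without WT_acetate 3.

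In KO mice under acetate alone, 23 of 24 cholesterol synthesis genes had a positive log2 fold against control, with a median of 0.21 (adjusted p = 0.321 with an estimated correlation). The acetyl-CoA acetyltransferase Acat2 was at 0.34 ± 0.09, Fdps at 0.30 ± 0.08 and the sterol sensor Insig1 at 0.34 ± 0.10. Genes of acetyl-CoA metabolism, a list that shares Acat2, had 29 of 34 positive (median 0.09), among them the isocitrate dehydrogenase Idh1 at 0.36 ± 0.09. Nuclear genes of oxidative phosphorylation had 81 of 84 positive (median 0.13), such as Ndufs7 at 0.20 ± 0.06. Glucocorticoid-responsive genes had 17 of 22 negative (median -0.31), such as the phagocytic receptor Mertk at -0.54 ± 0.14 and Angptl4 at -1.23 ± 0.35. No single gene passed in limma, with or without voom weights; the small ubiquitin-like modifier Sumo3, at 0.29 ± 0.06, and the lipoxygenase Alox12b, at -1.45 ± 0.31, had an adjusted p = 0.146, and 1940 genes had an unadjusted p under 0.05.

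All 4 lists passed with the preset correlation (adjusted p = 5.28e-10, adjusted p = 3.4e-05, adjusted p = 7.46e-15 and adjusted p = 9.58e-05). With an estimated correlation they gave adjusted p = 0.321 for cholesterol synthesis and adjusted p = 0.583 for each of the others; fry called the cholesterol list (adjusted p = 0.0211). With p adjusted over the list alone, 12 cholesterol genes, 2 acetyl-CoA genes and 0 oxidative phosphorylation genes passed as higher, and 10 glucocorticoid-responsive genes as lower with 1 higher. The cholesterol count was 0 without KO_control 4, 5 without KO_control 2 and 7 without KO_acetate 2 or KO_acetate 5. The acetyl-CoA count was 0 without KO_control 4 and 1 without KO_control 1, KO_control 3, KO_acetate 1 or KO_acetate 2. The oxidative phosphorylation count was 41 without KO_acetate 5, 9 without KO_acetate 2 and 5 without KO_control 3. The glucocorticoid counts were 0 lower and 1 higher without KO_control 1, whose absence left the list with an adjusted p = 0.488, and 7 lower without KO_acetate 1. Over all genes, 1 passed without KO_acetate 2, Alox12b (adjusted p = 0.0364), and 1 without KO_acetate 3.

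Among cell type markers in the same comparison, all 24 oligodendrocyte markers were positive (median 0.45), such as Opalin at 0.76 ± 0.36, and 17 of 19 striatal markers (median 0.54), such as Drd1 at 1.08 ± 0.40. Negative were 19 of 20 astrocyte markers (median -0.17), such as the connexin Gjb6 at -0.67 ± 0.20, and 14 of 22 endothelial markers (median -0.13), such as the lipid transporter Mfsd2a at -0.57 ± 0.15. The 4 lists passed with the preset correlation (adjusted p = 0.000634, adjusted p = 3.4e-05, adjusted p = 0.000103 and adjusted p = 0.0127) and not with an estimated correlation (adjusted p = 0.712, adjusted p = 0.583, adjusted p = 0.646 and adjusted p = 0.712). The oligodendrocyte list lost its call without KO_acetate 1 (adjusted p = 0.414) or KO_control 2 (0.122), the striatal list without KO_acetate 1 (0.604), and the endothelial list without KO_control 3 (0.452), KO_control 4 (0.0529), KO_acetate 2 (0.0891) or KO_acetate 5 (0.11). With p adjusted over each list, 0 oligodendrocyte, 0 striatal, 2 lower astrocyte and 4 lower endothelial genes passed. The striatal count was 1 without KO_acetate 1 or KO_acetate 3. The astrocyte count was 0 without KO_control 1, KO_control 3, KO_control 4 or KO_acetate 5, and 1 without KO_acetate 1, KO_acetate 2 or KO_acetate 4. The endothelial count was 0 without KO_control 1, 7 without KO_control 2, and 1 without KO_control 3, KO_acetate 2, KO_acetate 3 or KO_acetate 5.

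The interaction of genotype with acetate was positive for 27 of 29 immediate early genes, with a median of 0.90 (adjusted p = 5.72e-18 with the preset correlation and adjusted p = 0.513 with an estimated correlation). Sik1 was at 1.59 ± 0.40, Nr4a3 at 1.42 ± 0.39 and Junb at 1.28 ± 0.42. Adjusted over the list alone 5 members passed, all higher; over all genes 0 passed in limma, with or without voom weights, and 543 had an unadjusted p under 0.05. The list count was 1 without KO_control 1 or KO_acetate 2. It was 2 without WT_control 2, WT_control 4, WT_control 5, WT_control 6, KO_control 2, WT_acetate 1, the libraries labelled WT_acetate 4 or WT_acetate 5, or KO_acetate 4. It was 12 without KO_control 3 or WT_acetate 3, 13 without KO_acetate 1, 15 without WT_control 3 or the library labelled WT_acetate 2, and 19 without KO_control 4. All immediate early results given in the text, this interaction included, share the WT_control libraries, so they are not independent. In this interaction 8 lists passed with the preset correlation and 0 with an estimated correlation. Among them were oligodendrocyte (Opalin 1.16 ± 0.49), striatal (Drd1 1.08 ± 0.54) and meningeal markers (Col1a2 -0.47 ± 0.52). KO_acetate 1 stood apart with scores of 1.78 for oligodendrocyte and 2.56 for striatal markers.

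Between acetate with antibiotics and antibiotics alone, the list of cholesterol synthesis genes passed in the interaction with genotype (adjusted p = 0.0219 with an estimated correlation). That p was adjusted over the 45 lists of this comparison and not over the 16 comparisons. Within neither genotype did the cholesterol genes pass as a list with an estimated correlation (adjusted p = 0.056 in KO, adjusted p = 0.478 in WT). In KO, 23 of 24 were positive with a median of 0.19, such as Fdps at 0.33 ± 0.10, the demethylase Cyp51 at 0.36 ± 0.12 and Idi1 at 0.35 ± 0.13. In WT, 21 of 24 were negative with a median of -0.10, such as Mvk at -0.32 ± 0.09, the sterol oxidase Msmo1 at -0.30 ± 0.10 and Idi1 at -0.33 ± 0.12. The interaction was positive for 23 of 24, with a median of 0.28, and was 0.67 ± 0.18 for Idi1, 0.56 ± 0.15 for Msmo1 and 0.47 ± 0.13 for Mvk. In the interaction 24 lists passed with the preset correlation and 1 with an estimated correlation. Cell type markers were among the 24, such as microglia (C1qb 0.48 ± 0.19), oligodendrocyte (Hapln2 0.87 ± 0.74) and endothelial markers (Flt1 0.44 ± 0.25). So were blood (Alas2 1.12 ± 0.59), deep layer (Tle4 0.59 ± 0.30) and upper layer markers (Rasgrf2 -0.62 ± 0.28). Voltage-gated channel genes had 29 of 33 positive in WT (median 0.16), such as the potassium channel Kcnj3 at 0.29 ± 0.09 and the sodium channel Scn8a at 0.23 ± 0.08. Markers of other cells were mostly below 0 in WT: all 16 meningeal (median -0.64), all 24 oligodendrocyte (-0.38), all 6 blood (-0.56), 22 of 23 microglia (-0.14), 19 of 22 endothelial (-0.16), 13 of 15 pericyte (-0.19) and 17 of 20 astrocyte markers (-0.16). In WT, 24 lists passed with the preset correlation and 0 with an estimated correlation. The library labelled WT_abx 4 stood apart there, with scores of 2.2 for meningeal, 2.3 for choroid plexus and -0.199 for channel genes.

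The interaction of the cholesterol list passed with the preset correlation (adjusted p = 1.82e-18), with an estimated correlation (adjusted p = 0.0219) and with fry (adjusted p = 0.0215), and 8 members passed adjusted over the list alone, all higher. The estimated correlation and fry were not rerun with any library left out, the libraries labelled WT_abx 3 and WT_abx 4 included. Within KO the list passed with the preset correlation (adjusted p = 1.78e-15) and not with an estimated correlation (adjusted p = 0.056). Within WT the values were adjusted p = 4.85e-06 and adjusted p = 0.478. Over the list alone, 1 member passed as higher in KO and 1 as lower in WT. The KO count was 4 without KO_abx_and_acetate 1, 2 without KO_abx_and_acetate 4 and 0 without KO_abx 2, KO_abx 3, KO_abx_and_acetate 2 or KO_abx_and_acetate 3. The WT count was 3 without the library labelled WT_abx 3, 2 without WT_abx_and_acetate 4 and 0 without WT_abx 2, the library labelled WT_abx 4 or WT_abx_and_acetate 1. The channel list passed with the preset correlation (adjusted p = 2.88e-07) and not with an estimated correlation (adjusted p = 0.301), and 0 members passed over the list alone, against 6 without the library labelled WT_abx 3 and 4 without WT_abx_and_acetate 2.

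Over all genes, limma called 0 genes in KO, 0 in WT and 0 in the interaction, with or without voom weights, where 298, 910 and 561 had an unadjusted p under 0.05. In WT, 1 gene, Aldh4a1, passed without WT_abx_and_acetate 2 (adjusted p = 0.0484). Genes with the smallest p in KO included the chromatin protein Hmga2 at 1.51 ± 0.44 and the mitochondrial topoisomerase Top1mt at 0.36 ± 0.11, and in WT the proline catabolism enzyme Aldh4a1 at -0.39 ± 0.08.

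**Figure D2:**
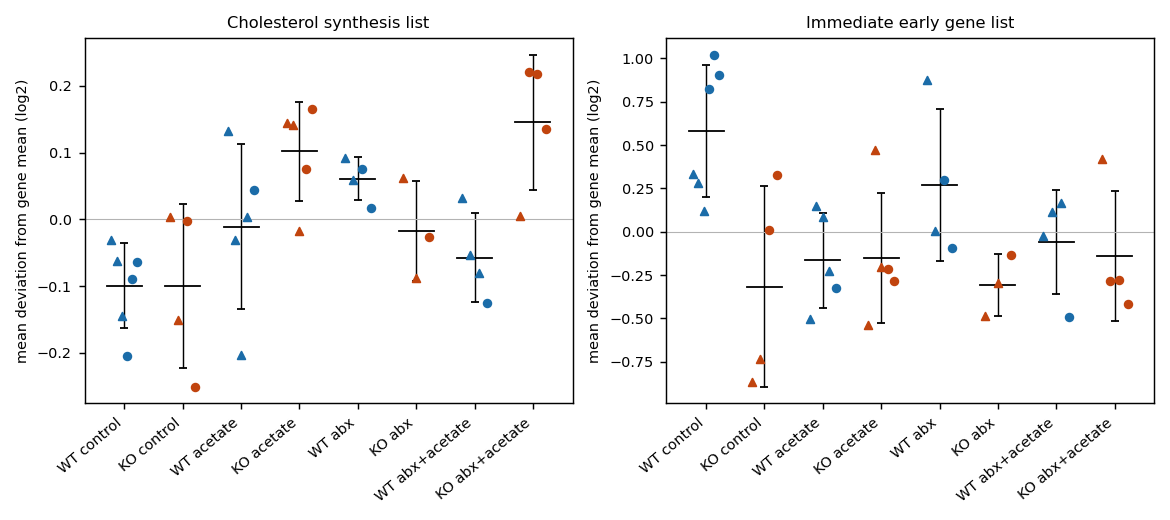
List scores of cholesterol synthesis genes (left) and immediate early genes (right) in each library, in log2 units on the vertical axes, by group on the horizontal axes; blue is WT, orange KO, circles are libraries labelled female, triangles male, and the black line and bars are the group mean ± SD. The mean cholesterol score was 0.145 in KO_abx_and_acetate and -0.0573 in WT_abx_and_acetate, and the mean immediate early score was -0.316 in KO_control and 0.58 in WT_control.

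Antibiotics with acetate, compared with control, gave the most genes of any comparison, in WT: limma called 108, of which 51 were higher and 57 lower, with 2136 at an unadjusted p under 0.05. Among the higher genes were the replication genes Ccne2, a cyclin, at 0.62 ± 0.13, Tipin at 0.57 ± 0.11 and Chrac1, a chromatin assembly subunit, at 0.59 ± 0.11, the transcription factor Klf11 at 0.62 ± 0.13, the serotonin receptor Htr1a at 0.61 ± 0.14 and Zbed5 at 0.76 ± 0.14. Among the lower genes were the clock gene Per2 at -1.12 ± 0.24, the collagen prolyl hydroxylase P4ha1 at -0.77 ± 0.16, the exchange factor Plekhg4 at -1.89 ± 0.34, the death receptor Tnfrsf25 at -1.55 ± 0.34, Phf21b at -0.93 ± 0.17 and the ciliary gene Cys1 at -0.85 ± 0.15. Their adjusted p lay between 0.0116 and 0.0289. Zbed5 was at 3.06 ± 0.25 in WT_abx_and_acetate (SD, n = 4) and 2.29 ± 0.15 in WT_control (SD, n = 6).

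Heat shock and protein folding genes had 23 of 25 negative log2 folds in this comparison (median -0.24), as had 27 of 29 immediate early genes (-0.65), 17 of 20 astrocyte (-0.15), 17 of 22 endothelial (-0.12) and 16 of 23 microglia markers (-0.09); 15 lists passed with the preset correlation and 0 with an estimated correlation. In the heat shock list the endoplasmic reticulum protein Creld2 passed over all genes at -0.74 ± 0.16 (adjusted p = 0.0288). That list passed with the preset correlation (adjusted p = 6.13e-09) and not with an estimated correlation (adjusted p = 0.795), and 11 members passed adjusted over the list alone, all lower. The count of 108 was 0 without WT_abx_and_acetate 3, 4 without WT_abx_and_acetate 1, 52 without WT_control 1, 63 without WT_control 2, 203 without WT_control 3, 23 without WT_control 4, 42 without WT_control 5 and 50 without WT_control 6. It was 45 from these groups alone, 56 with RIN added and 1002 with sample quality weights; centring the libraries gave 59 higher and 43 lower. With the title number range in the fit it was 75, of which 54 were shared; WT_abx_and_acetate has 3 low numbers and 1 high, and WT_control 1 low and 5 high. Of these genes, 54 were shared with RIN added and 18 from the groups alone. Creld2 lost its call without WT_control 1 (adjusted p = 0.0625), WT_control 4 (0.0665), WT_control 5 (0.0533), WT_abx_and_acetate 1 (0.116), WT_abx_and_acetate 2 (0.0551) or WT_abx_and_acetate 3 (0.0853).

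In KO mice under antibiotics with acetate, 22 of 24 cholesterol synthesis genes had a positive log2 fold against control, with a median of 0.28. Fdps and the squalene epoxidase Sqle were each at 0.45, with SE of 0.09 and 0.10, and the dehydrogenase Nsdhl at 0.32 ± 0.08. Fdps was at 5.80 ± 0.13 in KO_abx_and_acetate and 5.35 ± 0.08 in KO_control (SD, n = 4 each). Glucocorticoid-responsive genes had 18 of 22 negative (median -0.45), with Fkbp5 at -1.06 ± 0.31 and the kinase Map3k6 at -1.08 ± 0.29. Among cell type markers, 19 of 23 microglia (median 0.12) and 19 of 23 deep layer neuron markers (0.22) were positive, and 19 of 20 astrocyte (-0.12) and 15 of 16 meningeal markers (-0.68) negative; of 16 lists past the preset correlation, 1 passed with an estimated correlation. Limma called 0 genes, with or without voom weights, and 1104 had an unadjusted p under 0.05.

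The cholesterol list passed with the preset correlation (adjusted p = 2.05e-17), with an estimated correlation (adjusted p = 0.0272) and with fry (adjusted p = 0.0027). With p adjusted over the list alone, 12 members passed, all higher, and none over all genes; there were 7 without KO_control 4. The title number range is unbalanced here as well as sex: KO_abx_and_acetate has 3 females with low numbers (list scores 0.221, 0.218 and 0.136) and 1 male with a high number (0.00539), and KO_control 2 females and 2 males with 1 low number and 3 high. With the range in the fit beside sex, 10 members passed over the list alone and the median was 0.23 (adjusted p = 0.0426 with an estimated correlation). The glucocorticoid list passed with the preset correlation (adjusted p = 4.68e-09) and not with an estimated correlation (adjusted p = 0.363). Of it, 9 members passed adjusted over the list alone, all lower, against 0 without KO_control 1, 1 without KO_abx_and_acetate 4 and 15 without KO_control 2. The 3 cholesterol results that passed with an estimated correlation share the KO_abx_and_acetate libraries, and the 2 comparisons with control in KO share the KO_control libraries.

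Of the 45 lists in the 16 comparisons, 213 of 720 results passed with the preset correlation, 3 with an estimated correlation, 4 with fry and 13 with its mixed test. Each p was adjusted over the lists of its comparison and not over all 720 results. The lists of histone acetyltransferases and readers (21 measured) and of short-chain fatty acid receptors and transporters (8 measured) passed in no comparison with the preset correlation, where the smallest adjusted p was 0.178 and 0.245. Histone deacetylases (22 measured) passed in 2, and their smallest adjusted p was 0.655 with an estimated correlation.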

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

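Chosen after the result was seen were the tests of the labels, of WT_abx_and_acetate 3, of RNA integrity, of myelinating cells, and of sex and title numbers; the other tests here were set before their results were seen, on patterns and lists that were themselves chosen after their values were seen.

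The first pattern is Shank3 and Acr between the WT and KO levels in 3 libraries labelled WT. In the library labelled WT_acetate 5, Acr stood at 25.3% of the KO level and the Y-linked genes at 29.9% of the male level in a library labelled female, which argues against a single mutant allele in a female animal and is consistent with RNA of a male KO animal mixed in. In the libraries labelled WT_acetate 2 and WT_abx 4 the mean Acr share was 49.2%, a value that a single mutant allele in each animal needs. The higher of their mean Y-linked shares was 0.25%, which argues against an equal part of male KO RNA; an equal part of female KO RNA was not testable and stays open. The library labelled WT_acetate 2 is male by label, yet its mean Y-linked share was -1.55%, against its labelled sex. Whether it, or the libraries labelled WT_acetate 4 and WT_abx 3, carry a wrong label, treatment included, was not tested and stays open. The labels name no heterozygous group, so no biological explanation from the design was tested.

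The second pattern is the 108 genes of abx_and_acetate against control in WT. Their median absolute log2 fold was 0.416 (median SE 0.0953), against 0.411 without WT_abx_and_acetate 3 (SE 0.103), where 0 genes passed, and 0.412 with RIN in the fit (SE 0.0968), where 56 passed. The folds held while the errors grew, and the calls rest on small margins. The 108 genes were chosen as past the threshold in these same libraries, which favours genes with little spread between them. Mean RIN was also close, at 9.15 ± 0.13 in WT_abx_and_acetate and 9.05 ± 0.18 in WT_control (SD). Neither test could therefore readily lower the folds, so neither decides their cause. Of the 108, 90 (83.3%) had the same sign in KO, against a median of 52.5 and up to 95 in other splits of the KO libraries; 4 of 35 splits gave as many, the real split included, so an effect shared by both genotypes stays open.

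The third pattern is higher cholesterol synthesis genes in abx_and_acetate against control in KO. The list median of 0.277 was at its lowest 0.204, without KO_control 4, which argues against any single library as the whole cause. The oligodendrocyte list had a median of 0.0294, but its scores differ between the groups with an SE of 0.374, so more myelinating cells stay open. The list median was 0.277 with sex in the fit (0.29 without) and 0.229 with the title number range beside it. The list passed with an estimated correlation each time (adjusted p = 0.0272 and adjusted p = 0.0426). In KO_abx_and_acetate, though, the 3 females all have low numbers and the 1 male a high number. Sex and number range cannot be told apart within that group, and the fit takes their effects from other groups as well. These fits alone therefore cannot exclude either imbalance. An effect of acetate in KO may explain the pattern. In abx_and_acetate against abx in KO the list median was 0.193, reached by 1 of 35 splits (highest other 0.168). In acetate against control in KO it was 0.211, reached by 3 of 100 (highest other 0.223). Both counts were 1-sided, taking only medians as high, and 1 of 35 is the smallest share that those group sizes allow. This hypothesis was tested partly on the same data, since each of these 2 comparisons shares a group with the pattern. The list also passed with the preset correlation in abx against control, where no acetate was given, in both genotypes. In WT, Mvk was at 0.28 ± 0.08, Acat2 at 0.23 ± 0.09 and Nsdhl at 0.20 ± 0.07. In KO, Dhcr7 was at 0.19 ± 0.08, Acat2 at 0.20 ± 0.10 and Ebp at -0.24 ± 0.12. A change not particular to acetate or to KO therefore stays open.

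Other splits of the same libraries into groups of the same sizes were counted, the real split included. For KO against WT, 6 of 100 splits in control gave as many as the real 3 genes (highest other 202), 5 of 35 under abx as many as 2 (108), and 6 of 100 under acetate as many as 1 (89), so chance could not be excluded for the number of genes. This says nothing against Shank3 itself, which had the smallest exact p the group sizes allow in each treatment. Highest counts several times the real one may come from a structure of the samples other than their groups, which was not tested. For KO against WT under abx_and_acetate 1 of 35 splits gave as many as 2 genes (highest other 0). Over treatments 3 of 100 gave as many as 3 (highest other 44), where 44 may also come from such a structure. For the 108 genes of abx_and_acetate against control in WT it was 1 of 100 (highest other 4), and for the 1 gene of acetate against control in WT 3 of 100 (highest other 1). The shares of these 4 comparisons are under 0.05 taken singly but are not adjusted for the 16 comparisons, so these counts of splits alone do not exclude chance. For abx against control in KO, 2 of 35 splits gave as many as 2 genes (highest other 4), and chance could not be excluded.

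A real count of 0 is reached by every split, so the number of splits tests nothing in these comparisons: abx against control in WT (100 of 100, highest other 4), acetate against control in KO (100 of 100, highest other 27), abx_and_acetate against abx in WT (35 of 35, highest other 2) and in KO (35 of 35, highest other 1), and abx_and_acetate against control in KO (35 of 35, highest other 0). So too the interactions of genotype with abx (100 of 100, highest other 443), with acetate (100 of 100, highest other 241) and with abx_and_acetate against abx (100 of 100, highest other 11). The splits with 27, 443, 241 and 11 genes may come from a structure of the samples, which was not tested. Limma gave 1345, 1940, 910, 298, 1104, 368, 543 and 561 genes at an unadjusted p under 0.05 in these 8 comparisons, in this order. With voom weights, too, 0 genes passed the adjusted threshold in each.

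Splits were also counted for 4 list medians, chosen among 720 list results after their values were seen, so small shares do not exclude chance. The immediate early median of -0.97 in KO against WT in control was reached in size by 2 of 100 splits (highest other 1.07). The cholesterol medians were 0.204 in KO against WT under abx_and_acetate (1 of 35, highest other 0.2), 0.277 in abx_and_acetate against control in KO (1 of 35, highest other 0.259) and 0.276 in the interaction (2 of 100, highest other 0.28). The cholesterol interaction was singled out because it passed as a test of the difference between KO and WT itself. Its adjusted p = 0.0219 with an estimated correlation was adjusted over the lists of that comparison only.

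A single library stood apart within its group for 19 of 353 pairs of a gene and a group, by the gap to the nearest other library over the group's range; chance flags about 1 in 20 groups, or 17.7 here. The ratio was 0.875 for Acr, highest in the library labelled WT_abx 4, and 0.883 for Gpatch1, lowest there. In KO_acetate 1 it was 0.73 for Drd2, 0.786 for Lrrc10b, 0.806 for Rarb and 0.805 for Ndufa9, each highest. Drd2, Lrrc10b and Rarb belong to the striatal list, whose score was 2.56 in KO_acetate 1. A total near 17.7 does not make each of these gaps a chance gap. The lowest library gave 0.739 for Fgl1 in KO_acetate 4, 0.737 for Lad1 in KO_acetate 3 and 0.92 for Ndufs7 in KO_control 3. The highest gave 0.83 for Dph1 in KO_control 1, 0.839 for Fkbp5 in KO_abx_and_acetate 3, 0.839 for Selplg in KO_abx_and_acetate 2 and 0.855 for Ggt1 in KO_abx_and_acetate 4. In WT_abx_and_acetate it was 0.834 for Cys1 (highest, library 4), 0.838 for Plekhg4 (lowest, library 1), 0.853 for Rbm11 (lowest, library 4) and 0.858 for Zc3h6 (lowest, library 2). In WT_control it was 0.628 for Mreg (highest, library 3) and 0.641 for Zbed5 (lowest, library 4).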

How the results depend on the processing

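The settings that leave out sets of libraries were chosen after seeing the data, the others before. KO against WT in acetate gave 2 genes in place of 1 with no sex term, a pseudocount of 1, quality weights, voom weights, without the 4 libraries against their sex label and without both sets, and 4 without the 3 of intermediate Shank3. Acetate against control in WT gave 7 in place of 1 with no sex term, 2 with RIN, the title range or the filter on low genes, 67 with quality weights, and 0 with a pseudocount of 1, voom weights, the groups alone, without the 4 or without both sets. Abx against control in KO gave 0 in place of 2 with RIN, the title range, a pseudocount of 1, voom weights or the groups alone, and 1 with 1 prior variance. The 108 genes of abx_and_acetate against control in WT became 163 with no sex term, 56 with RIN, 1002 with quality weights, 45 from the groups alone and 75 with the title range or without both sets.

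Fitted alone, the groups gave 23 genes in KO against WT in control, 1 in KO against WT in abx and 1 in abx_and_acetate against abx in WT. Quality weights gave 4 in abx against control in WT and 1 in abx_and_acetate against control in KO; 1 prior variance gave 1 in genotype by abx. The correlation of genotype effects between abx and acetate, -0.0969, was 0.0859 without the 4 and 0.102 without both sets, and -0.25 to 0.00287 over the libraries left out in turn.

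Leaving out each library in turn gave 1 to 3 genes in KO against WT in abx, 1 to 2 in acetate and in abx_and_acetate, 2 to 3 in control, 3 to 5 over treatments, 0 to 1 in abx against control in WT, 0 to 1 in KO, 0 to 6 in acetate against control in WT, 0 to 1 in KO, 0 to 1 in abx_and_acetate against abx in WT, 0 to 203 in abx_and_acetate against control in WT and 0 to 1 in genotype by abx. The list glucocorticoid-responsive genes in KO vs WT in control turned direction without KO_control 1 (adjusted p = 0.82; over the libraries left out, 3.87e-11 to 0.82). The lists were not run with voom weights. In the other settings and with libraries left out, they were tested with the preset correlation only. The estimated correlation and fry were rerun only for cholesterol synthesis in abx_and_acetate against control in KO, with other covariates. No paired analysis was possible because the labels give no shared replicate numbers, and the cause of these dependences was not tested.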

Other observations

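The test near Shank3 was set before its result was seen, and the list described here was chosen after its values were seen. Genes of histone methylation and chromatin remodelling had 34 of 37 interaction terms below 0 between genotype and abx_and_acetate against abx, with a median of -0.13. The list passed with the preset correlation (adjusted p = 5.17e-08) and not with an estimated correlation (adjusted p = 0.354).

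Genes within 5 Mb of Shank3 had an unadjusted p under 0.05 over treatments in 5 of 64 cases (7.81%), against 5.20% of 14362 other genes. Of 100 regroupings 31 gave a share as large, the highest being 25%, so an excess in this share cannot be told from chance. The 5 genes were Acr (4.51 ± 0.35), C730034F03Rik (0.84 ± 0.16), Phf21b (-0.26 ± 0.09), Ncaph2 (-0.06 ± 0.02) and Arsa (0.10 ± 0.05). The share weighs neither the size of an effect nor its distance from Shank3. It therefore says nothing against the differences in Acr and C730034F03Rik, which lie close to Shank3.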
